A study of Mus musculus with 12 samples.

How the data were processed

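Chromatin immunoprecipitation with sequencing (ChIP-seq) was made from primary mouse embryonic fibroblasts (MEFs) of a hybrid 129 and B6 background. The series held 12 samples, of which 8 were ChIP libraries and 4 were input libraries (chromatin sequenced without an antibody). The ChIP libraries covered 2 histone marks, trimethylated lysine 4 of histone H3 (H3K4me3) and trimethylated lysine 27 (H3K27me3). Each mark was measured in 4 conditions, wild type (WT) and lincRNA-p21 knockout (KO) MEFs, each mock treated or treated with doxorubicin, a DNA-damaging drug, at a labelled dose of 0.5 mM for 24 h. The dose is printed as labelled, and whether its unit is a slip for a micromolar dose was not determined. Chromatin was fixed in 1% formaldehyde for 10 min and sonicated to 300 to 500 bp, per the labels' protocols. Each condition and mark had 1 library, so no spread between replicates could be measured and no p-value between conditions was computed.

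A peak list was used for each of the 8 ChIP libraries, and read-level data and the input libraries were not analysed here. Bowtie 0.12.7, MACS 1.4.2 and the mouse build mm9 are named in the submitters' processing notes. The deposited lists give for each peak a position, a peak number and a score, and their numbering follows MACS, which writes a p-value there on a negative logarithmic scale. The score is the authors' own value for the peak and was used to describe, rank or filter peaks within a list. An exception is the ranking of the highest-scoring regions found in all 4 libraries. It used the mean over the 4 libraries of the highest score in the region, although score levels differ between lists. No list held a score under 80. Peaks at repeats or at places of known artefact signal were not filtered out here. Scores piled up at a ceiling of 3100, so that ranks at the top of the H3K4me3 lists were often tied. Read depth per library is unknown, since the lists give no read counts. The intervals printed are exact (Clopper-Pearson) 95% binomial intervals and cover counting error over peaks only, not the spread between cultures or libraries. Neighbouring peaks are not independent of each other, so that these intervals are too narrow even for that purpose.

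Coordinates are those of mm9, printed counting from 1 on the assumption that the deposited starts count from 0. Peaks were compared by overlap, and an overlap of at least 1 bp counted as shared. A peak of the second library of a comparison without an overlapping peak in the first was called gained, and a peak of the first without one in the second was called lost. These words describe presence in a list and not a tested change. Regions were also made by joining overlapping peaks of a mark over its 4 libraries. H3K4me3 peaks that overlapped an H3K27me3 peak of the same condition were counted as carrying both marks. For changed peaks, the share at the other mark was set beside 10000 random lists of peaks from the same library, matched on score (20 bins) and width (3 bins). Such a comparison describes these libraries and is not a test between conditions.

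The comparisons were doxorubicin against mock in each genotype and KO against WT in each treatment. The rule for naming regions, fixed before the data were examined along with the comparisons, the patterns of presence over the 4 conditions, the overlap rule and the first set of alternatives, took for each mark and comparison the 5 gained and the 5 lost peaks with the highest score. For each mark it also took the 5 longest and the 5 highest-scoring regions found in all 4 libraries. The share of changed H3K4me3 peaks at H3K27me3 peaks, the H3K27me3 share within each pattern of presence, the counts by H3K27me3 status and score, the matched random lists, the peak widths and the 1 Mb windows were chosen after the data had been seen. Gene lists, promoters and the targeted locus, which were also planned, were not analysed here, because no mm9 annotation was used and coordinates were not converted between builds. For the same reason no region is given a gene name, exon or intron.

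Alternatives were a score of at least 100, an equal number of highest-scoring peaks from every list of a mark, changed peaks within the upper 50% of their list by score, an overlap of at least 50% of a peak, sharing within 1 kb, and joining peaks less than 3 kb apart. In lists of equal number, gains and losses can differ only where a peak of 1 list overlaps several of the other. Their balance in that setting therefore shows no direction of change. The overlap, distance, joining and length rules were tested on simulated peaks built from a list of 14897 peaks, and each of the 7 rules gave back the number put in. Of 200 simulated classes of 800 peaks drawn by score alone, 3.5% lay above the 95th percentile of their matched random lists. The computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.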

Results

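The 8 peak lists showed where H3K4me3, a mark of active or poised promoters, and H3K27me3, the mark laid down by Polycomb repressive complex 2, were detected in WT and lincRNA-p21 KO MEFs with and without doxorubicin. LincRNA-p21 is a long noncoding RNA induced by p53, and the series title sets its question as the role of this RNA in the expression of Polycomb target genes and in the G1/S checkpoint. The H3K4me3 lists held 14897 peaks in WT mock, 16477 in WT doxorubicin, 14326 in KO mock and 15095 in KO doxorubicin cells. The H3K27me3 lists held 16160, 17517, 16580 and 17828 peaks in the same order. With 1 library per mark and condition, none of the differences given here has a replicate check, and differences in read depth or enrichment between libraries are part of each of them. Of the 40 gained or lost H3K4me3 peaks that the naming rule took, 2 lay within 1 kb of a peak of the compared library, and of the 40 H3K27me3 peaks 11 did.

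H3K4me3 regions were largely shared by the 4 conditions, and H3K27me3 regions were more variable and included the widest domains. Of 16628 H3K4me3 regions, 13107 (78.8%) were present in all 4 libraries and 9.79% in 1 library. Of 24298 H3K27me3 regions, 6335 (26.1%) were present in all 4 libraries and 44.1% in 1 library. The H3K27me3 lists had median scores of 141 to 155, near the score floor of 80, and the H3K4me3 lists 1162 to 2141. Gained and lost H3K27me3 peaks had median scores of 103 to 109 in the comparisons below. The variability of H3K27me3 was therefore not separated from that of peaks listed near this floor. Of the peak numbers in the H3K27me3 lists 39.0 to 47.2% were missing, against 6.83 to 10.3% in the H3K4me3 lists. If the missing numbers were peaks scored under 80, a gained or lost H3K27me3 peak may have been called in the compared library and left out there. H3K4me3 covered 33.4 Mb in WT mock, 32.1 Mb in WT doxorubicin, 27.1 Mb in KO mock and 29.2 Mb in KO doxorubicin cells. H3K27me3 covered 48.0 Mb, 39.0 Mb, 36.3 Mb and 35.9 Mb in the same order, so that WT mock had the longest coverage for both marks. The median H3K27me3 peak was 2015 bp, 1475 bp, 1391 bp and 1310 bp wide in that order, narrower than the median H3K4me3 peak of the same condition at 2029 bp, 1734 bp, 1723.5 bp and 1777 bp. Peaks wider than 10 kb numbered 495, 286, 287 and 228 for H3K27me3 and 9, 6, 1 and 2 for H3K4me3.

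The longest H3K4me3 region common to the 4 conditions lay on chromosome 18 from 75525564 to 75539728, where a single peak spanned 13671 bp in WT mock, 14165 bp in WT doxorubicin, 13170 bp in KO mock and 13025 bp in KO doxorubicin cells. The next longest were on chromosome 5 from 143572631 to 143586095, on chromosome 5 from 123584037 to 123595274, on chromosome 1 from 82278852 to 82289865 and on chromosome 17 from 34251526 to 34262417. The longest H3K27me3 region common to the 4 conditions was an 86.3-kb domain on chromosome 15 from 102731780 to 102818052. Peaks covered 86.0 kb of it in WT mock, 79.4 kb in WT doxorubicin, 86.0 kb in KO mock and 79.5 kb in KO doxorubicin cells. The other long H3K27me3 domains lay on chromosome 7 from 86636805 to 86704989, on chromosome 19 from 44788501 to 44852735, on chromosome 4 from 115598608 to 115657006 and on chromosome 11 from 96021946 to 96080039. The highest-scoring H3K27me3 regions common to the 4 conditions were 12.7 to 22.2 kb long and were led by chromosome 19 from 16939512 to 16957945 and chromosome 9 from 99762331 to 99781433. The highest-scoring H3K4me3 regions, led by chromosome 5 from 129525205 to 129528314 and chromosome 8 from 124113684 to 124116599, had scores at or above the ceiling in the 4 libraries.

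Doxorubicin against mock in WT cells asked where DNA damage changed the marks while lincRNA-p21 was present. With doxorubicin 1359 H3K4me3 peaks were gained (8.25% of the doxorubicin list, 95% interval 7.83 to 8.68) and 329 were lost (2.21% of the mock list, 1.98 to 2.46). The highest-scoring gain was on chromosome 3 from 96077308 to 96079014, with a score of 1701 and no peak in either mock library. It was followed by chromosome 6 from 112438833 to 112441156 (score 898), chromosome 9 from 44531544 to 44535413 (740.05), chromosome 19 from 48279295 to 48281234 (735) and chromosome 9 from 49232286 to 49235459 (638). The gains on chromosomes 6 and 19 overlapped H3K27me3 peaks present in all 4 conditions. The highest-scoring loss lay close to the strongest gain, on chromosome 3 from 96081566 to 96082833, with a score of 411, and was followed by chromosome X from 54032621 to 54034957 (314) and chromosome 4 from 88772227 to 88774523 (309). Each of these places had H3K4me3 in KO mock and KO doxorubicin cells, so that the WT doxorubicin list alone lacked them. Of the gained H3K4me3 peaks 37.4% (34.8 to 40.0) overlapped an H3K27me3 peak of the same condition, above the 22.6 to 29.4% of the matched random lists. Of the lost peaks 11.9% (8.57 to 15.8) did, below the 24.6 to 41.3% of theirs. Most changed peaks had low scores, with a median of 121 for gains. Just 1 gain and 0 losses were in the upper 50% of their lists. With equal numbers of top peaks there were 382 gains and 653 losses, a balance that by construction shows no direction.

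For H3K27me3 in WT cells, 5134 peaks were gained with doxorubicin (29.3%, 28.6 to 29.99) and 5721 were lost (35.4%, 34.7 to 36.1). The 4 highest-scoring gains lay side by side on chromosome 11, led by the peaks from 96146259 to 96153836 (score 1161) and from 96129180 to 96134899 (741). All 4 fell within 87.7 kb in which the WT mock library had no peak and the KO mock library had 85.0 kb covered. The fifth was on chromosome 3 from 30402740 to 30406461 (604). The highest-scoring losses were on chromosome 4 from 34008065 to 34014764 (679), chromosome 6 from 83169511 to 83176990 (602), chromosome 19 from 59534100 to 59538933 (593) and from 59523248 to 59528919 (589), and chromosome 15 from 102929508 to 102935662 (585). The nearest WT doxorubicin peak to the loss on chromosome 4 was 680594 bp away. The 2 losses on chromosome 19 and the loss on chromosome 15 were also absent in KO doxorubicin cells. Joining peaks less than 3 kb apart left 3124 gains and 3419 losses.

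Doxorubicin against mock in KO cells put the same question without lincRNA-p21. Here 1335 H3K4me3 peaks were gained (8.84%, 8.40 to 9.31) and 385 were lost (2.69%, 2.43 to 2.97), none of them in the upper 50% of its list by score. With equal numbers of top peaks 803 were gained and 565 were lost. The strongest gain was again on chromosome 3, from 96077290 to 96079069, with a score of 1408. The other leading gains were on chromosome 4 from 155572799 to 155575206 (1403), chromosome 16 from 23609685 to 23612362 (1334), chromosome 17 from 4626136 to 4626732 (1166) and chromosome 15 from 102802549 to 102805019 (1067). Of these, the peak on chromosome 4 lay 251 bp from a KO mock peak, and the regions on chromosomes 4 and 16 already had H3K4me3 in both WT libraries. The leading losses were on chromosome 7 from 85722455 to 85723998 (387), chromosome 6 from 149514097 to 149515281 (376), chromosome 6 from 6812569 to 6814074 (327), chromosome 3 from 34548464 to 34550619 (317) and chromosome 8 from 15010872 to 15012566 (294). All 5 had H3K4me3 in both WT libraries, and 4 of the 5, the exception being chromosome 6 from 149514097, lay at H3K27me3 in all 4 conditions. The share at H3K27me3 peaks had the opposite order to that in WT. It was 15.5% (13.6 to 17.6) for gained peaks, below the 24.7 to 31.2% of the matched lists, and 58.2% (53.1 to 63.2) for lost peaks, above the 24.7 to 40.0% of theirs. The difference between the genotypes was not tested.

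For H3K27me3 in KO cells, 6297 peaks were gained (35.3%, 34.6 to 36.0) and 5646 were lost (34.1%, 33.3 to 34.8). The leading gains included 3 neighbouring peaks on chromosome 2, from 74572316 to 74581129 (866), 74581151 to 74585593 (768) and 74586111 to 74591569 (684), all of which had H3K27me3 in both WT libraries. A gain on chromosome 7 from 89676458 to 89681953 (798) was absent from the 3 other lists. The leading losses included 3 neighbouring peaks on chromosome 15, from 102820785 to 102823541 (617), 102824700 to 102830550 (737) and 102833138 to 102843662 (709), all with H3K27me3 in both WT libraries. Joining peaks less than 3 kb apart left 3511 gains and 3185 losses. With equal numbers of top peaks there were 5288 gains and 5745 losses, a balance that by construction shows no direction.

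KO against WT in mock-treated cells asked what the loss of lincRNA-p21 did to the marks without induced damage. H3K4me3 was listed at fewer places in KO cells, with 278 peaks gained (1.94%, 1.72 to 2.18) and 1389 lost (9.32%, 8.86 to 9.80). The strongest loss was on chromosome 5 from 37259203 to 37261931, with a score of 1548, a place with H3K27me3 in all 4 conditions and the nearest KO mock H3K4me3 peak 36773 bp away. It was followed by chromosome 9 from 50560863 to 50563638 (1154), chromosome 5 from 114539915 to 114542001 (1081), chromosome 15 from 102750317 to 102753127 (1076) and chromosome 16 from 5146200 to 5147980 (954), each of which had H3K4me3 again in KO doxorubicin cells. The leading gains were on chromosome 2 from 98502240 to 98503302 (648), chromosome 9 from 35112356 to 35113327 (557), chromosome 8 from 110068974 to 110070981 (352), chromosome 5 from 45189367 to 45191058 (337) and chromosome 11 from 103221322 to 103222253 (283). The places on chromosomes 2 and 11 also had H3K4me3 in WT doxorubicin cells. Artefact signal at these places was not checked. Of the lost peaks 42.3% (39.7 to 45.0) were at H3K27me3, above the 32.0 to 38.2% of the matched lists, and of the gained peaks 18.7% (14.3 to 23.8), below the 21.9 to 41.4% of theirs. Within the upper 50% of the lists there were 0 gains and 1 loss, and with equal numbers of top peaks 414 gains and 959 losses.

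For H3K27me3 in mock cells, 4229 peaks were gained in KO (25.5%, 24.8 to 26.2) and 5864 were lost (36.3%, 35.5 to 37.0). The highest-scoring gain was a 530-bp peak on chromosome 17 from 29215682 to 29216211, with a score of 2937. It was the sole H3K27me3 peak of the 4 lists narrower than 1000 bp with a score of 800 or more, and all 4 H3K4me3 libraries had a peak at the same place. The next 4 gains lay on chromosome 11 in the stretch without WT mock peaks, from 96198054 to 96208469 (1737), 96122223 to 96128957 (1368), 96152731 to 96167490 (1147) and 96168054 to 96196420 (594). The leading losses were on chromosome 6 from 100082820 to 100087563 (518.01), chromosome 11 from 84433738 to 84439502 (518), chromosome 17 from 25656835 to 25662680 (511), chromosome 1 from 187316865 to 187322192 (476) and chromosome 5 from 122439874 to 122445117 (463). None of these 5 places had H3K4me3 in any condition, and the first lay 79 bp from a KO mock H3K27me3 peak. Joining peaks less than 3 kb apart left 2703 gains and 3501 losses.

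**Figure D1:**
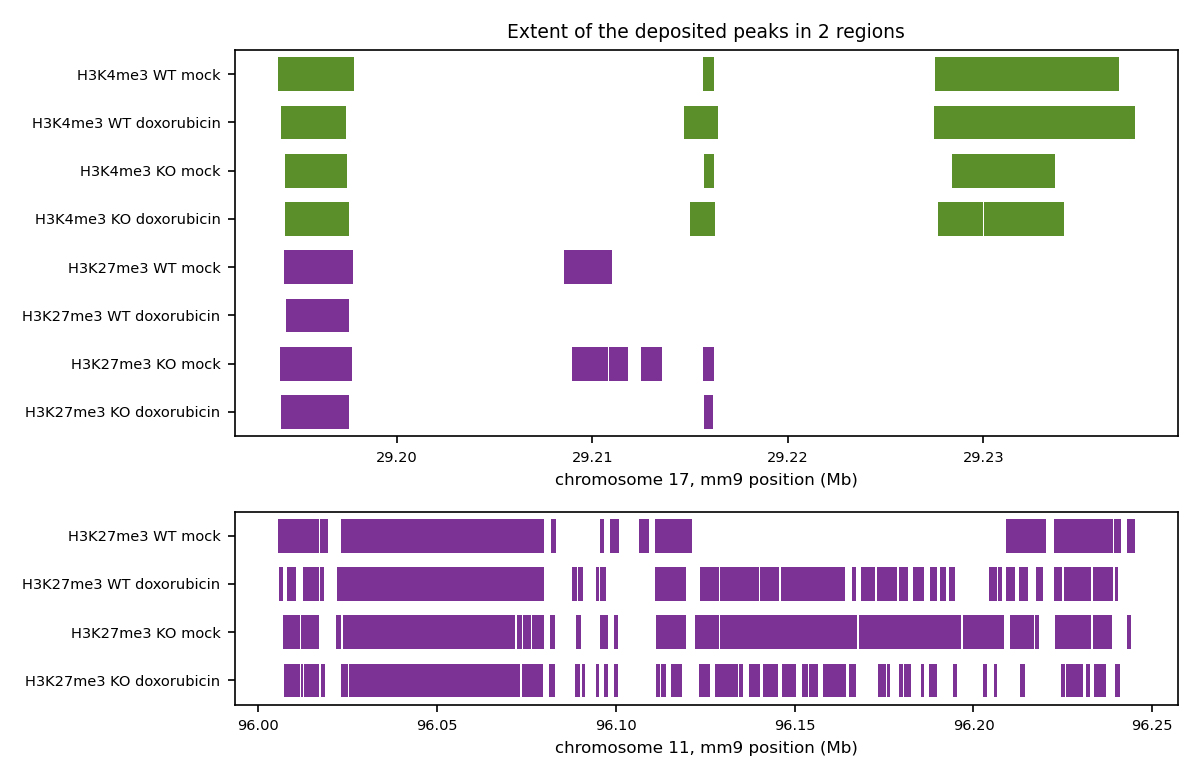
Extent of the deposited peaks along mm9 positions in Mb, with H3K4me3 in green and H3K27me3 in purple, 1 row per library. In the upper map of chromosome 17 the narrow H3K27me3 peak of KO mock cells near 29215682 lies under H3K4me3 peaks of all 4 conditions, and in the lower map of chromosome 11 WT mock cells have no H3K27me3 peak from 96121286 to 96208980.

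KO against WT in doxorubicin-treated cells asked the same under DNA damage. KO cells had 665 H3K4me3 peaks gained (4.41%, 4.08 to 4.75) and 1967 lost (11.9%, 11.4 to 12.4). The strongest loss was again on chromosome 5, from 37259022 to 37261890, at the score ceiling of 3100. It was followed by chromosome 4 from 21605028 to 21607403 (2382), chromosome 4 from 137949583 to 137952822 (2379), chromosome 7 from 85721590 to 85724367 (2008) and chromosome 18 from 67292330 to 67294383 (1988). All 5 places had H3K27me3 in the 4 conditions and H3K4me3 in both WT libraries, and the nearest KO doxorubicin H3K4me3 peak was 8089 bp away or further. The leading gains were on chromosome 1 from 92738070 to 92740864 (1477), chromosome 17 from 4626136 to 4626732 (1166), chromosome 7 from 108542618 to 108544659 (985), chromosome 5 from 45189154 to 45191313 (747) and chromosome 16 from 10446354 to 10448210 (714), and none of these had H3K27me3 in any condition. The places on chromosomes 1, 7 and 16 also had H3K4me3 in WT mock and KO mock cells, so that the WT doxorubicin list alone lacked them. The peak on chromosome 17 was 597 bp wide and in no other H3K4me3 list. Of the lost H3K4me3 peaks 53.9% (51.7 to 56.1) were at H3K27me3, against 24.96 to 30.4% of the matched lists. Of the gained peaks 4.06% (2.69 to 5.85) were, against 20.8 to 32.5%. Within the upper 50% of the lists there were 0 gains and 11 losses, and with equal numbers of top peaks 944 gains and 974 losses.

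For H3K27me3 in doxorubicin-treated cells, 5746 peaks were gained in KO (32.2%, 31.5 to 32.9) and 6191 were lost (35.3%, 34.6 to 36.1). The highest-scoring gain, on chromosome 8 from 86937025 to 86942113 (1121), lay 17 bp from a WT doxorubicin peak, and a further gain, on chromosome 12 from 40858890 to 40861486 (470), lay 49 bp from one. Gains on chromosome 7 from 89676458 to 89681953 (798) and from 89687281 to 89691469 (540) lay 86935 bp or more from any WT doxorubicin peak. The leading losses were on chromosome 6 from 124814119 to 124818651 (545), chromosome 8 from 13241586 to 13246495 (515, 297 bp from a KO doxorubicin peak), chromosome 8 from 4222392 to 4225442 (419), chromosome 15 from 102945104 to 102947166 (407) and chromosome 15 from 78472523 to 78475960 (405). All 5 had H3K27me3 in KO mock cells. Joining peaks less than 3 kb apart left 3346 gains and 3528 losses.

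**Figure D2:**
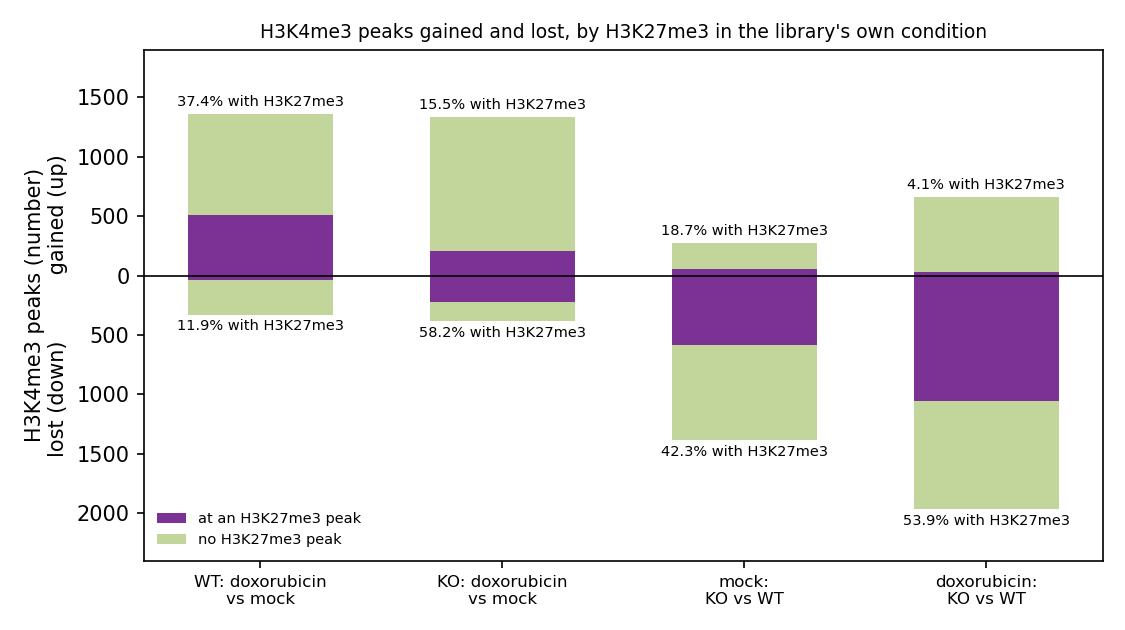
Number of H3K4me3 peaks gained (up) and lost (down) in each of the 4 comparisons, split into peaks that overlap an H3K27me3 peak of the same condition (purple) and peaks that do not (green). H3K27me3 was at 53.9% of the 1967 peaks lost in KO doxorubicin cells and at 4.06% of the 665 gained.

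The places where H3K4me3 was missing in KO cells were thus counted by their H3K27me3 status. Of the 2389 WT doxorubicin H3K4me3 peaks with H3K27me3 in all 4 conditions, 996 were absent in KO doxorubicin cells (41.7%, 39.7 to 43.7). Of the 13180 without H3K27me3 in any condition, 831 were absent (6.31%, 5.90 to 6.73). In mock cells the numbers were 531 of 1965 (27.02%, 25.1 to 29.05) and 752 of 12115 (6.21%, 5.78 to 6.65). In the other direction, 1.22% (0.714 to 1.95) of KO doxorubicin H3K4me3 peaks with H3K27me3 in all 4 conditions and 4.80% (4.43 to 5.18) of those without it were absent in WT doxorubicin cells. In mock cells these were 2.50% (1.76 to 3.44) and 1.82% (1.59 to 2.08). Absence was concentrated among low scores at both kinds of place. In the lowest 10% of the WT doxorubicin list by score 92.4% of the peaks with H3K27me3 and 48.8% of those without were absent in KO. In the third 10% these were 46.5% and 3.29%. The gap was smaller in mock cells, with 76.4% and 61.4% in the lowest 10% and 6.97% and 1.61% in the third. The gap was also found within a genotype, but in WT cells in 1 direction and in KO cells with a size that depended on the direction. Of the WT doxorubicin H3K4me3 peaks 19.05% (17.5 to 20.7) with H3K27me3 in all 4 conditions and 5.96% (5.57 to 6.38) without it were absent in WT mock cells. Of the KO mock peaks 14.7% (12.9 to 16.6) and 1.24% (1.06 to 1.46) were absent in KO doxorubicin cells. In the opposite directions, 1.48% (0.991 to 2.11) and 2.34% (2.08 to 2.63) of WT mock peaks were absent in WT doxorubicin cells, and 11.1% (9.54 to 12.9) and 8.30% (7.82 to 8.79) of KO doxorubicin peaks in KO mock cells.

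**Figure D3:**
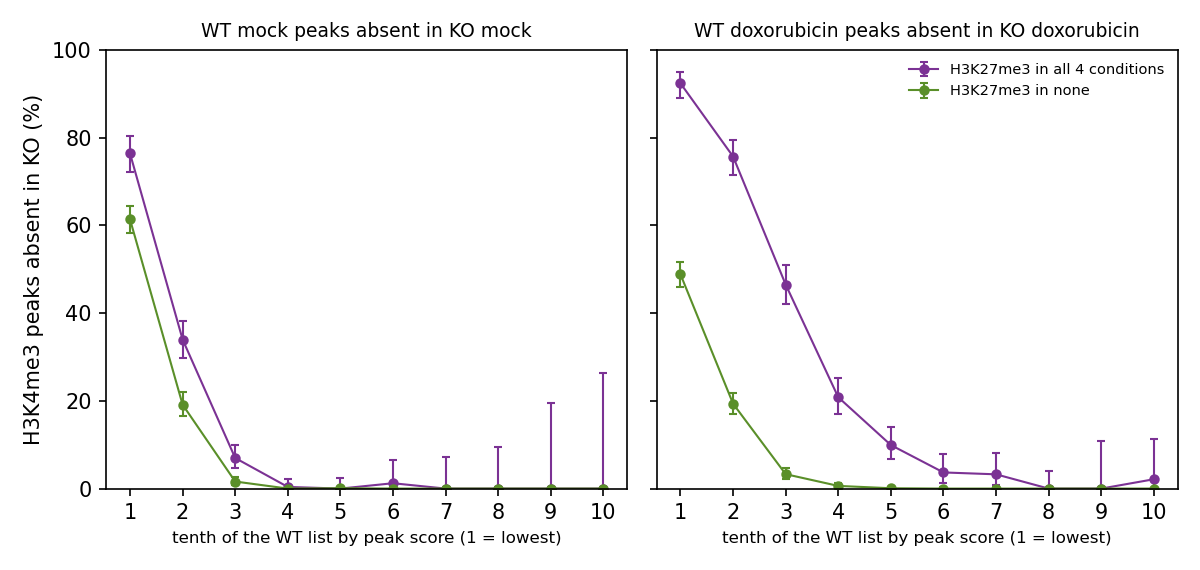
Share of WT H3K4me3 peaks (percent) absent in KO cells of the same treatment, in 10% steps of the WT list from lowest to highest score. Purple points are peaks with H3K27me3 in all 4 conditions, green points those with it in none, and bars are exact 95% binomial intervals. In the lowest 10% the shares were 92.4% and 48.8% in doxorubicin-treated and 76.4% and 61.4% in mock cells.

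The pattern of presence over the 4 conditions compared the doxorubicin response between genotypes. For H3K4me3, 686 peaks were in both WT and neither KO library and 72 in both KO and neither WT library. A further 231 were in both doxorubicin and neither mock library and 22 in both mock and neither doxorubicin library. The 2 crossed patterns, which neither treatment nor genotype alone predicts, held 77 peaks (WT mock and KO doxorubicin) and 43 peaks (WT doxorubicin and KO mock). Among the 686 peaks of WT cells, 389 (56.7%, 52.9 to 60.5) lay at H3K27me3 in all 4 conditions, and of the 110 with a score of 500 or more 99 (90.0%) did. They were led by chromosome 5 from 37259022 to 37261890, chromosome 4 from 137949583 to 137952822, chromosome 2 from 162484906 to 162487478, chromosome 6 from 126592773 to 126596089 and chromosome 2 from 146909348 to 146911576. Among the 72 peaks of KO cells 3 (4.17%, 0.868 to 11.7) did. The matched lists gave 20.4 to 32.8% for the 686 peaks and 6.94 to 45.8% for the 72. The share was also high in 1 crossed pattern, with 19 of the 43 peaks of WT doxorubicin and KO mock cells (44.2%, 29.1 to 60.1). This was near the upper end of the 2.33 to 48.8% in its matched lists. The share was 0 of 77 in the other crossed pattern (matched lists 9.09 to 45.5%). It was 15 of 231 (6.49%) in both doxorubicin libraries (13.9 to 31.6%) and 3 of 22 (13.6%) in both mock libraries (0 to 63.6%). For H3K27me3 the corresponding counts were 1394 (WT), 708 (KO), 1009 (doxorubicin), 1091 (mock), 776 and 676 (crossed). With equal numbers of top peaks, the H3K4me3 counts were 413 for WT, 156 for KO, 47 for doxorubicin, 56 for mock and 139 for WT mock with KO doxorubicin.

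Places with both marks, a state often called bivalent and frequent at developmental genes, were fewer in KO cells. H3K27me3 overlapped 2420 H3K4me3 peaks in WT mock (16.2%, 15.7 to 16.8), 2692 in WT doxorubicin (16.3%, 15.8 to 16.9), 1907 in KO mock (13.3%, 12.8 to 13.9) and 1815 in KO doxorubicin cells (12.0%, 11.5 to 12.6). The length carrying both marks was 3.22 Mb, 3.30 Mb, 1.98 Mb and 1.69 Mb in the same order. H3K4me3 peaks with both marks were narrower than the others, with a median of 1330 bp against 1824 bp in WT doxorubicin cells and 1145 bp against 1873 bp in KO doxorubicin cells. H3K27me3 peaks with both marks were wider than the others, with 3369.5 bp against 1366 bp and 2675 bp against 1246 bp in the same libraries.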

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

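The bound for the share of strong H3K27me3 peaks was set before its result was seen, and the other tests in this part were chosen after the results were seen. Several summary values moved in opposite directions with doxorubicin in the 2 genotypes, each from 1 library per condition, and none of these differences was tested. The length covered by H3K4me3 changed by -1.29 Mb in WT and by 2.17 Mb in KO cells. The median H3K4me3 width changed by -295 bp in WT and by 53.5 bp in KO cells. The share of H3K4me3 peaks with H3K27me3 changed by 0.093 percentage points in WT, well within its counting interval, and by -1.29 in KO cells. With equal numbers of top peaks, H3K4me3 peaks with H3K27me3 numbered 2251 in WT mock and 2135 in WT doxorubicin cells. They numbered 1899 in KO mock and 1588 in KO doxorubicin cells, so that the directions in this setting were not opposite. The share of H3K27me3 peaks with H3K4me3 changed by 0.161 percentage points in WT and by -0.909 in KO cells. Among 13755 H3K4me3 peaks matched one to one, the WT mock peak was wider than the WT doxorubicin peak in 72.5%, with a median difference of 162 bp over all matched peaks, and among 12922 in KO cells the mock peak was wider in 36.7%. The WT peak was wider than the KO peak in 85.7% in mock (median difference 309 bp) and in 53.5% in doxorubicin (27 bp). WT mock H3K27me3 peaks were wider than those of WT doxorubicin in 74.3% and of KO mock in 78.4%. The width change in WT thus cannot be told apart from a property of the 1 WT mock library of each mark.

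H3K4me3 peaks of WT cells that were missing in KO cells lay at H3K27me3 peaks more often than others. Dropout of weak or narrow peaks alone is argued against, since 53.9% of the doxorubicin losses were at H3K27me3 and the highest of 10000 lists matched on score and width reached 30.4%. In mock cells the margin was smaller, with 42.3% against 38.2%. Shares above the matched lists were also found within a genotype, for KO losses (58.2% against 40.0%) and WT gains (37.4% against 29.4%) with doxorubicin. WT losses (11.9%) and KO gains (15.5%) with doxorubicin lay below theirs. Such an excess is thus not particular to the comparison of genotypes. Carry-over of H3K27me3 chromatin or reads into the WT H3K4me3 libraries stays open. Of the highest-scoring 25% of H3K27me3 peaks without KO H3K4me3, 15.5% had a WT H3K4me3 peak. This is under the bound of 50% set beforehand to exclude carry-over. That bound was wrong because the share reached 72.4% (71 of 98) at scores of at least 2000, as a low level of carry-over would also give. Width was not held fixed in these shares, and wider peaks overlap others more easily. In WT doxorubicin cells the median H3K27me3 score was 126 at 1 to 2 kb and 1744 at 10 to 20 kb. The rise of the share with score therefore cannot decide on carry-over. A difference between the WT and KO cultures other than the genotype cannot be told apart from the genotype, since the design has 1 library per condition and 56.7% of the 686 peaks of both WT and neither KO library, from both treatments, lay at H3K27me3. A dependence of H3K4me3 at H3K27me3-marked places on lincRNA-p21 is the biological hypothesis that the design gives, but it remains untested against these explanations and against variation between libraries, since peaks with H3K27me3 were absent more often than those without also from WT doxorubicin to WT mock (19.05% against 5.96%) and from KO mock to KO doxorubicin cells (14.7% against 1.24%), though not or less so in the opposite directions (1.48% against 2.34% and 11.1% against 8.30%).

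The 530-bp H3K27me3 peak of KO mock cells on chromosome 17 from 29215682 to 29216211 had the highest score per bp of its list, as had the 582-bp WT mock H3K4me3 peak at the same place in its own list. A WT doxorubicin H3K4me3 peak reached 1013 bp beyond its left edge, which argues against a left flank without alignable reads, but the furthest reach beyond its right edge was 236 bp, so that such a right flank stays open. Extra copies of a short DNA stretch in a library stay open, since the edges of the 6 peaks at this place spread over 1046 bp, and those of the 4 peaks under 1000 bp, whose closeness their selection partly sets, over 60 bp. The KO mock H3K4me3 peak there had a score of 175, so that the 2 marks of these cells did not share the high score. No WT H3K27me3 library had a peak there and KO doxorubicin had one of 470 bp with a score of 99.5. Whether the place lies in or near the targeted locus was not determined, so that the genotype, including sequence of the targeted allele, may also matter and was not tested.

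The stretch of 87.7 kb on chromosome 11 from 96121286 to 96208980 had no H3K27me3 peak in WT mock cells, where WT doxorubicin, KO mock and KO doxorubicin cells had 64.0 kb, 85.0 kb and 46.8 kb covered. The peaks on either side, with scores of 1138 and 1014, carried consecutive peak numbers with 0 missing between them, which argues against a peak taken out with the scores under 80. Low scoring of very wide regions by the peak caller stays open. WT mock H3K27me3 peaks of 30 kb or more had a median score of 827 against 1556 for those of 10 to 20 kb, in the same order as in the 3 other libraries. The medians were 869 for 5 to 10 kb and 106 for 1 to 2 kb, so that very wide peaks were not low in general. The widest, of 83.2 kb, had a score of 100. The 3 other libraries had the same order and still had peaks in the stretch, so that this order cannot decide. In the 86.3-kb domain on chromosome 15 the WT mock list held 2 peaks with a highest score of 295. WT doxorubicin, KO mock and KO doxorubicin held 13, 5 and 7 peaks there, with highest scores of 1767, 2371 and 1474. Low scoring of a very wide WT mock peak thus occurred in that domain, which does not decide the question for the stretch. A biological absence of the mark in untreated WT cells was not tested, and the gap adds to the H3K27me3 gains with doxorubicin in WT and with KO in mock cells.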

How the results depend on the processing

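The alternatives for the share of changed H3K4me3 peaks at H3K27me3 were chosen after seeing the data and the others before. The next counts are in the order doxorubicin against mock in WT, the same in KO, KO against WT in mock and KO against WT in doxorubicin. Restricting changes to the upper 50% of each list left 1, 0, 0 and 0 H3K4me3 gains and 0, 0, 1 and 11 losses. For H3K27me3 it left 955, 1355, 678 and 1154 gains and 1096, 1090, 1070 and 1212 losses. This setting takes in fewer peaks by construction. Beyond that, nearly all H3K4me3 changes and most H3K27me3 changes lay in the lower 50% of their lists by score. It left H3K4me3 patterns of 1 (both doxorubicin), 0 (both mock), 5 (both WT), 0 (both KO), 0 and 0 (crossed), and H3K27me3 patterns of 247, 300, 296, 176, 165 and 139 in that order. The share at H3K27me3 was then 0% of the 1 WT gain with doxorubicin and 100% of the losses in KO in mock and in doxorubicin. With equal numbers of top peaks, WT doxorubicin gains were 382 and losses 653, KO doxorubicin gains 803 and KO losses in doxorubicin 974. H3K27me3 with doxorubicin in KO gave 5288 gains and 5745 losses. The balance of gains and losses in this setting is set by how peaks are split, and no direction was read from it. The H3K4me3 patterns were then 47, 56, 413, 156 and 139. The shares at H3K27me3 were then 58.4% of WT doxorubicin gains, 17.2% of WT doxorubicin losses, 47.2% of KO losses in mock and 74.9% of KO losses in doxorubicin. Joining peaks less than 3 kb apart left 3124, 3511, 2703 and 3346 H3K27me3 gains, 3419, 3185, 3501 and 3528 losses, H3K27me3 patterns of 556, 578, 721, 424, 448 and 362, and 25 H3K4me3 peaks of WT doxorubicin with KO mock. It gave shares of 65.7% for KO doxorubicin losses and 60.2% for KO losses in doxorubicin, and sharing within 1 kb gave 63.8% and 58.4% for these. A score of at least 100 gave 41.1% of WT doxorubicin gains, 67.4% of KO doxorubicin losses and 57.6% of KO losses in doxorubicin, and left 11 H3K4me3 peaks of both mock libraries. The cause of these moves was not tested. All 36 values with a 50% overlap, 34 with sharing within 1 kb, 52 with the stricter score, 27 with equal numbers and 31 with joined peaks stayed within 1.5 times the reported count or within the interval of the reported share. The upper-50% setting gave no value for places with both marks. Other promoter windows and the alternatives for fixed gene lists were not run. Unknown read depth limits every count. No fit that pairs the treatments within genotype or the genotypes within treatment was made. Each condition had 1 library and the labels carry no replicate numbers.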

Other observations

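The regions and windows in this part were chosen after the data had been seen. The fourth widest H3K4me3 peak of WT doxorubicin cells lay on chromosome 17 from 29227490 to 29237747, 10258 bp at the score ceiling. In the same interval WT mock cells had 9373 bp in 2 peaks, KO mock cells 5278 bp in 1 peak and KO doxorubicin cells 6411 bp in 2 peaks. The widest peak there ranked 35 by width in the WT mock list, 109 in the KO mock list and 500 in the KO doxorubicin list, and no H3K27me3 library had a peak in the interval. These ranks are of single peaks, and the split into 2 peaks lowers them in WT mock and KO doxorubicin cells. The length covered was larger in KO doxorubicin than in KO mock cells. Whether this interval lies near the targeted locus was not determined. To its left, H3K4me3 and H3K27me3 peaks overlapped in all 4 conditions, in WT doxorubicin cells from 29194073 to 29197416 and from 29194352 to 29197566.

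Over windows of 1 Mb, the H3K27me3 length on chromosome 14 from 47000001 to 48000000 was 10.5 kb in WT mock, 42.3 kb in WT doxorubicin, 15.5 kb in KO mock and 58.0 kb in KO doxorubicin cells. On chromosome 8 from 10000001 to 11000000 it was 16.1 kb, 41.2 kb, 16.6 kb and 48.3 kb in that order, against the shorter total coverage of both doxorubicin lists. The H3K27me3 length on chromosome 15 from 102000001 to 103000000, which holds the 86.3-kb domain, was 313 kb, 206 kb, 248 kb and 176 kb in that order. The H3K4me3 length in this window was 91.9 kb, 93.3 kb, 67.0 kb and 84.0 kb. On chromosome 2 from 74000001 to 75000000 the H3K4me3 length was 33.6 kb, 28.7 kb, 21.6 kb and 18.7 kb, lower in KO than in WT with either treatment. The H3K4me3 length on chromosome 9 from 3000001 to 4000000 was 6.62 kb and 5.78 kb in the WT libraries and 20.9 kb and 10.98 kb in the KO libraries. Whether repeats or artefact signal contribute to this window was not checked.

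Chromosome X held 3.08%, 3.05%, 3.12% and 3.24% of the H3K4me3 peaks in WT mock, WT doxorubicin, KO mock and KO doxorubicin cells and 0.402%, 0.394%, 0.458% and 0.471% of the H3K27me3 peaks. The widest H3K27me3 peak of WT mock cells, 83.2 kb on chromosome 15 from 102734883 to 102818052, had a score of 100.04. Of the peak numbers given in the H3K27me3 lists 39.0 to 47.2% were missing, and in the H3K4me3 lists 6.83 to 10.3%.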
